A study of Mus musculus with 6 samples.

How the data were processed

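Bulk RNA sequencing was used to compare mouse tendon stem/progenitor cells, a fibroblast-like population grown from tendon that can form tendon, bone, cartilage and fat cells in culture. Per the labels' protocols, cells of the Col1a1 lineage were separated by flow cytometry into a Vldlr-positive and a Vldlr-negative population and were then kept in serum-containing culture medium, RNA was extracted with Trizol, and libraries were made with a SMARTER mRNA library kit. The genotype labels carry a different number after Col1 alpha in each sample and were read as 1 genotype, Col1a1-Cre with a YFP reporter, because the cell type label is Col1a1 in all 6. Vldlr is the very low density lipoprotein receptor, a member of the LDL receptor family. Each population had 3 libraries. The labels do not say whether these came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. A difference in donor or culture between the groups could therefore not be told apart from the sort label, for any gene or list.

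The deposited table gave RPKM (reads per kilobase of exon, scaled to library size) for 15711 genes in each of the 6 libraries; the table itself names no unit, and the unit was worked out from the values. Per the submitters' processing notes, the genome build was mm10 and the software included Cell Ranger and bcl2fastq 1.8.4, with no role stated. The aligner, the counting program, the handling of reads that match several genes and the use of strand are not given in the sources used here. Genes with near-identical copies, such as Gapdh with its pseudogenes or the Ifit3 pair, and overlapping genes are therefore uncertain. 20 gene names had been turned into dates and could not be matched to a gene length.

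Exon lengths were taken from GENCODE release M21, on the GRCm38 assembly that mm10 names, as the merged exons of each gene. When each RPKM value was multiplied by this length, the values of each library were whole multiples of 1 step, so that reads per gene could be worked out. 15690 of the 15691 genes with a length came out as whole reads in all 6 libraries, with a tolerance of 0.01 reads. The exception was Vldlr, whose values were off whole reads in the 3 labelled-negative libraries. Whether a unit is a read or a read pair is not known. The worked-out reads summed to 17287209, 17348846 and 17280540 in labelled-negative replicates 1 to 3 and to 17660241, 17691122 and 17719560 in labelled-positive replicates 1 to 3, and 1 read in a 1 kb transcript was worth 0.0537 to 0.0608 RPKM. The deposited RPKM had been divided by library sizes that carry composition factors from 0.928 to 1.07, and trimmed-mean factors computed here from the reads came to 0.928 to 1.07 as well.

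The design fixed before the data were examined assumed read counts; because the table held RPKM, the rule fixed for normalized values was used in its place. Genes at 1 RPKM or more in at least 3 libraries (12116 genes) were tested with limma 3.58.1 in R 4.3.3 (trend and robust options, statmod 1.5.0) on log2(RPKM + 1). The 2 groups were the only term, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. A log2 fold change on this scale understates the change of genes with low RPKM. Folds in the text are ratios of mean RPKM, and a fold against a group with 0 reads is a lower bound computed against 3 reads over the group, which covers counting error only. Values are means ± SD over 3 libraries. Vldlr and Col1a1 were also compared by an exact two-sided permutation test, which with 3 against 3 cannot give a p under 0.1.

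27 gene lists were part of that design, and the 24 with at least 5 tested members were compared with all other genes by limma's camera test with an inter-gene correlation preset to 0.01. The tests were repeated with fry and with an estimated correlation. With the latter, camera takes its degrees of freedom from the 6 libraries and not from the number of genes. Fry is a rotation test that asks whether the genes of a list move, on balance, one way. It does not compare them with other genes. Named genes followed a rule of the same design. Vldlr and Col1a1 were always named. The 12 largest rises and 12 largest falls were taken among called genes with a log2 fold change of at least 1 in size, a mean of at least 5 RPKM (written as CPM in the rule, which assumed counts), no overlap between the groups and no predicted gene model. From each list up to 4 called members with the lowest adjusted p were named, or up to 2 of the highest mean where fewer than 2 were called, and for lists of other cell types also the 2 of the highest mean. Some genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

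The alternatives chosen with that design were median-ratio, upper-quartile and total-read scaling, a pseudocount of 0.1, no filter and a filter at 5 RPKM, limma voom on the worked-out reads, the replicate number as a block, and leaving out each library in turn. Negative binomial count tests were not run on the worked-out reads, because the rule fixed for normalized values was followed. A test against a 1.5-fold change and a recalculation with 5 RPKM added to Vldlr in the labelled-negative libraries were added after seeing the data. On simulated reads for this comparison with 200 changed genes (11893 genes tested), the main test recovered 91.0% of the genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and called 18 of 11695 unchanged genes. Every simulated gene had the same dispersion (0.00247), whereas the data had uneven replicate noise and many more genes called. These rates may therefore not hold for the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps. All value columns of the table were used.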

Results

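The series held 6 RNA libraries from mouse Col1a1-lineage tendon stem/progenitor cells, 3 from cells sorted as Vldlr-positive and 3 from cells sorted as Vldlr-negative, and its stated aim was to learn what Vldlr-positive cells do in tendon regeneration. The groups are named here as labelled, because the level of Vldlr itself could not serve as a check of the labels, as described for that gene. Depth was even, with 17280540 to 17348846 worked-out reads per labelled-negative library and 17660241 to 17719560 per labelled-positive one. Replicates differed by more than counting noise, with a chi-square per gene of 2.50 to 5.22 among the labelled-negative libraries and 2.34 between labelled-positive replicates 2 and 3. Labelled-positive replicate 1 stood apart from these 2, with 14.6 and 12.5. Mitochondrial genes took 2.58% to 2.92% of the reads in the labelled-negative libraries and 1.59% to 1.95% in the labelled-positive ones.

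Vldlr (chromosome 19, 27216484 to 27254231, GRCm38) was listed at 4.13 ± 0.532 RPKM in the labelled-positive libraries and at 0.796 ± 0.285 RPKM in the labelled-negative ones (n = 3 each). As listed this was 5.19-fold higher (log2 fold change 1.52, SE 0.13, limma adjusted p = 2.1e-05; exact permutation p = 0.1, the smallest that 3 against 3 allows). The 3 labelled-negative values, 0.961, 0.959 and 0.467 RPKM, were the only values among all genes with a length that did not equal a whole number of reads. They became whole, at 1118, 1117 and 1025 reads, when 5 RPKM was added to each. With that amount added, Vldlr was at 5.80 ± 0.285 RPKM in the labelled-negative libraries, 1.40-fold above the labelled-positive ones (log2 fold change -0.41, SE 0.08, limma adjusted p = 0.0035), so the direction of Vldlr rests on these 3 values and no direction is drawn from it. Col1a1 (chromosome 11, 94936224 to 94953042), the collagen chain whose promoter marks the lineage, was at 3027 ± 119 RPKM in the labelled-positive and 1789 ± 86.2 RPKM in the labelled-negative libraries. This was 1.69-fold higher (log2 fold change 0.76, SE 0.07, limma adjusted p = 3.1e-05; exact permutation p = 0.1). It did not pass a test against a 1.5-fold change (adjusted p = 0.150).

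On the log2(RPKM + 1) scale, which ranks the genes here, the largest rise in the labelled-positive libraries was that of Thbs4 (chromosome 13, 92751590 to 92794818), a thrombospondin of tendon matrix, at 1011 ± 49.1 against 2.23 ± 0.133 RPKM, 453-fold higher (log2 fold change 8.29, SE 0.06, adjusted p = 6.4e-11). Cilp, a cartilage and tendon matrix protein, rose 421-fold to 58.5 ± 4.34 RPKM (log2 fold change 5.70, SE 0.07), the collagenase Mmp13 rose 36.7-fold to 213 ± 3.20 RPKM, and Prg4, which encodes the joint lubricant lubricin, rose 33.2-fold to 95.1 ± 3.60 RPKM. The other genes among the 12 largest rises were Cadm4, Sox10, Angpt4, Ltbp2, Ngfr, Angptl7, Gap43 and Crispld2, with log2 fold changes from 3.53 for Crispld2 to 4.77 for Cadm4. The largest fall on that scale was that of H19 (chromosome 7, 142575529 to 142578143), an imprinted long non-coding RNA, at 499.5 ± 19.3 RPKM in the labelled-negative and 4.11 ± 0.501 RPKM in the labelled-positive libraries (122-fold lower, log2 fold change -6.62, SE 0.08, adjusted p = 5.2e-10). The angiotensin receptor gene Agtr2 (chromosome X, 21484544 to 21489164) was 217-fold lower, at 0.515 ± 0.0924 against 112 ± 6.21 RPKM, and the glypican gene Gpc3 (chromosome X, 52272426 to 52613950) was 260-fold lower, at 0.218 ± 0.114 against 56.6 ± 2.43 RPKM. Ptn, a secreted heparin-binding growth factor, fell from 388 ± 5.12 to 11.6 ± 1.51 RPKM. The other 8 of the 12 largest falls were Cyp2f2, Cd36 and 6 macrophage genes (Ctss, C1qa, C1qb, C1qc, Tyrobp and Fcer1g).

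Of 12116 genes tested with limma, 3602 were higher and 3167 lower in the labelled-positive libraries at an adjusted p under 0.05, among them 411 at least 2-fold higher and 472 at least 2-fold lower. These counts depend on the scaling: with libraries scaled by total reads only, 1875 genes were higher and 5547 lower, and the log2 fold changes of all genes moved by a median of -0.17. Genes at least 2-fold lower numbered 728 with a pseudocount of 0.1 and 763 with limma voom. Against a 1.5-fold change, 537 genes were higher and 606 lower.

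**Figure D1:**
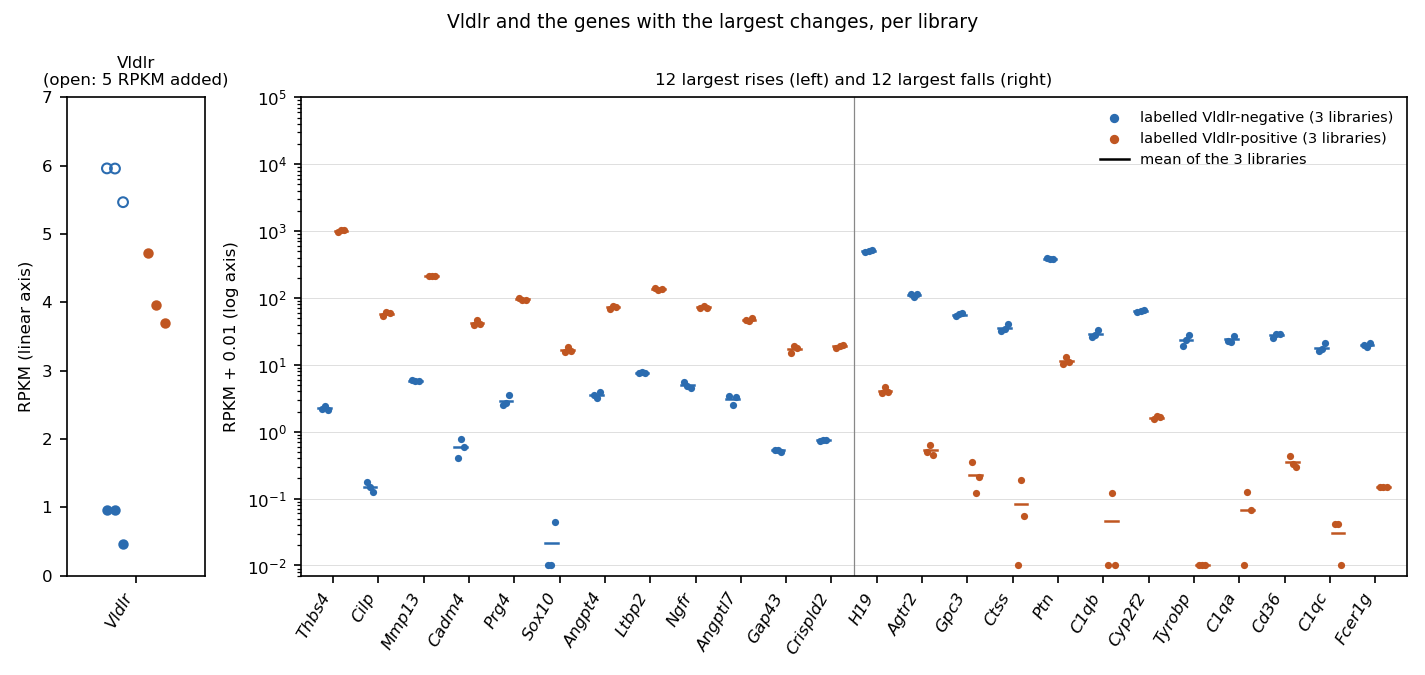
RPKM per library of Vldlr (left panel, linear axis) and of the 12 largest rises and 12 largest falls (right panel, RPKM + 0.01 on a log axis); blue points are the 3 labelled-negative and orange points the 3 labelled-positive libraries, short lines are group means, and open circles are the labelled-negative Vldlr values with 5 RPKM added. The groups do not overlap for any of the 24 genes, as the rule that chose them required. Labelled-negative Vldlr lies below the labelled-positive libraries as listed and above them with 5 RPKM added.

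Tendon and matrix genes were mostly higher in the labelled-positive libraries. In the tendon lineage list, 10 of 15 tested genes rose, 4 fell and 1 did not pass (10 up and 4 down adjusted over the list alone), and camera gave an adjusted p of 0.028, against an adjusted p = 0.155 with an estimated correlation. Besides Thbs4, the collagen-binding proteoglycan gene Fmod rose 11.0-fold to 3152 ± 113 RPKM, Comp, a pentameric matrix protein, rose 7.80-fold to 2615 ± 207 RPKM, and the transcriptional coactivator gene Eya2 rose 4.30-fold to 9.31 ± 0.346 RPKM. The 4 that fell, named after their values were seen, were Tnmd, a marker of mature tendon cells, 3.95-fold lower at 6.88 ± 0.803 RPKM, and Eya1, Tgfbr2 and Kera, 4.37-fold, 2.16-fold and 1.63-fold lower. Of 25 collagens and structural matrix genes, 17 rose, 5 fell and 3 did not pass (18 up and 5 down adjusted over the list alone; camera adjusted p = 3.6e-04, adjusted p = 0.155 with an estimated correlation). Col15a1 rose 9.28-fold, fibronectin (Fn1) and the proteoglycan gene Prelp each rose 3.57-fold, and Col6a2 rose 2.74-fold.

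The contractile and TGF-beta response list had 12 of 16 genes that rose, 0 that fell and 4 that did not pass (12 up and 0 down adjusted over the list alone; camera adjusted p = 1.2e-05, adjusted p = 0.155 with an estimated correlation). Ltbp2, which binds microfibrils, rose 17.7-fold, the collagen receptor subunit Itga11 10.2-fold and the matricellular gene Ccn2 3.51-fold. With total-read scaling, 12 genes of this list rose and 3 fell.

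Genes of other mesenchymal fates moved in different directions. In the osteogenic list, 7 of 9 genes rose, 1 fell and 1 did not pass (7 up and 1 down adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.155 with an estimated correlation). Osteopontin (Spp1) was 10.2-fold higher at 2353 ± 123 RPKM, alkaline phosphatase (Alpl) 28.6-fold higher at 11.4 ± 0.949 RPKM, Ibsp 7.34-fold higher and the bone transcription factor gene Sp7 21.1-fold higher at 3.00 ± 0.315 RPKM. The 1 that fell, named after its values were seen, was Bglap2. It was at 0.683 RPKM in the labelled-positive and 2.81 RPKM in the labelled-negative libraries. In the adipogenic list, 9 of 12 genes fell, 2 rose and 1 did not pass (9 down and 2 up adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.155 with an estimated correlation). The fatty acid transporter gene Cd36 was 80.4-fold lower, the lipid droplet gene Plin1 14.6-fold lower, adiponectin (Adipoq) 9.92-fold lower and lipoprotein lipase (Lpl) 3.48-fold lower; Cd36 and Lpl are also made by macrophages, whose marker genes fell in the same libraries. The 2 adipogenic genes that rose, named after their values were seen, were the transcription factor genes Pparg and Cebpb. Pparg was at 11.7 RPKM in the labelled-positive and 5.18 RPKM in the labelled-negative libraries, and Cebpb at 30.5 and 19.4 RPKM. Of 8 chondrogenic genes 3 rose and 4 fell (3 up and 4 down adjusted over the list alone; camera adjusted p = 0.782). Prg4 was higher and Hapln1, Col10a1 and Sox5 lower. Of 17 mesenchymal stem and progenitor markers 7 rose and 9 fell (7 up and 9 down adjusted over the list alone; camera adjusted p = 0.710). Ngfr rose 14.5-fold, Nes 13.6-fold and Mcam 6.18-fold, while Cd34 was 4.13-fold lower. Ngfr and Nes are also markers of Schwann cells and Mcam of vascular cells, and the Schwann and endothelial lists rose in the same libraries, with median log2 fold changes of 2.37 and 1.11. With total-read scaling, 4 progenitor markers were higher and 9 lower. The matrix proteases and inhibitors list was also divided, with 7 of 18 genes higher and 8 lower (8 up and 8 down adjusted over the list alone; camera adjusted p = 0.909). Mmp13 and Timp1 were higher and Adamts9 and Timp3 lower. With upper-quartile scaling 8 genes of the protease list were higher and 7 lower, and with total-read scaling 5 were higher and 9 lower. For the chondrogenic, progenitor and protease lists the median log2 fold changes were -0.19, -0.24 and -0.03, the means 0.29, 0.14 and 0.25, and camera pointed down where fry pointed up. These medians turned positive for the chondrogenic and protease lists without the low-value filter (0.03 and 0.06) and for the chondrogenic and progenitor lists with the 5 RPKM filter (0.01 and 0.12). The protease median was 0.00125 without labelled-positive replicate 3.

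Cholesterol synthesis and fatty acid genes were mostly lower in the labelled-positive libraries, while the LDL receptor family and reelin list was not called. In the cholesterol synthesis list, 17 of 21 genes fell, 0 rose and 4 did not pass (17 down and 0 up adjusted over the list alone; camera adjusted p = 1.2e-06, adjusted p = 0.103 with an estimated correlation). Squalene epoxidase (Sqle) was 2.11-fold lower, the synthase gene Hmgcs1 2.18-fold lower, the sterol sensor gene Insig1 2.04-fold lower and Hsd17b7 2.01-fold lower. Against a 1.5-fold change, 5 of the 21 fell and 0 rose. Of 17 fatty acid uptake and oxidation genes 10 fell and 3 rose (10 down and 3 up adjusted over the list alone; camera adjusted p = 0.0094, adjusted p = 0.156 with an estimated correlation). Cpt1a, which brings fatty acids into mitochondria, was 1.53-fold lower, Acadm 1.64-fold lower and Ppargc1a 4.92-fold lower. Cd36, which macrophages also make, is in this list too and had its largest fall (log2 fold change -4.41). With total-read scaling, 11 genes of this list fell and 0 rose, and 1 rose when any of the 6 libraries except labelled-negative replicate 3 and labelled-positive replicate 1 was left out. In the LDL receptor family and reelin list 3 of 12 genes rose and 5 fell (3 up and 6 down adjusted over the list alone; camera adjusted p = 0.113). With total-read scaling 1 rose and 7 fell, and 1 rose when any of the 6 libraries except labelled-positive replicate 1 was left out. Apolipoprotein E (Apoe), which macrophages also make, was 4.89-fold lower and Mylip 2.10-fold lower. Vldlr counts among the 3 as listed; with 5 RPKM added to it in the labelled-negative libraries, 2 rose and 6 fell, and the camera adjusted p was 0.0229, against an adjusted p = 0.178 with an estimated correlation.

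Cell cycle genes were higher in the labelled-positive libraries. 21 of 25 rose, 1 fell and 3 did not pass (21 up and 1 down adjusted over the list alone; camera adjusted p = 4.2e-06, adjusted p = 0.155 with an estimated correlation). The mitotic genes Plk1, Ccnb2 and Cdc20 were 3.20-fold, 2.43-fold and 2.36-fold higher and the nucleotide synthesis gene Rrm2 1.86-fold higher. E2f1 fell, and Mki67, Mcm4 and Ccne1 did not pass, all named after their values were seen. Against a 1.5-fold change, 4 of the 25 rose and 0 fell. In the cell cycle arrest and p53 targets list, 8 of 15 genes fell and 3 rose (8 down and 3 up adjusted over the list alone; camera adjusted p = 0.0933). The cell cycle inhibitor genes Cdkn1a and Cdkn2a were lower, Cdkn1a 1.76-fold lower at 113 ± 7.43 RPKM and Cdkn2a 2.06-fold lower at 39.1 ± 5.76 RPKM. The 3 that rose, named after their values were seen, were Trp53 and the inhibitor genes Cdkn2b and Cdkn2c. Cdkn2b was at 110 RPKM in the labelled-positive and 95.1 RPKM in the labelled-negative libraries, and Cdkn2c at 11.1 and 8.66 RPKM. With total-read scaling, 11 genes of this list fell and 0 rose. Of 16 hypoxia and glycolysis genes 14 rose and 2 fell (14 up and 2 down adjusted over the list alone; camera adjusted p = 8.4e-05, adjusted p = 0.199 with an estimated correlation). The glycolytic genes Pfkfb3, Pfkl and Pgk1 were 3.15-fold, 2.30-fold and 2.29-fold higher, while the vasodilator peptide gene Adm was 2.02-fold lower.

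More genes of the Wnt pathway fell than rose, and more genes of the Notch pathway rose than fell. In the Wnt pathway list, 9 of 15 genes fell, 4 rose and 2 did not pass (9 down and 4 up adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.191 with an estimated correlation). The secreted Wnt inhibitor genes Dkk2 and Sfrp1 were 10.5-fold and 7.50-fold lower, the Wnt target gene Nkd1 was 4.37-fold lower and its paralog Nkd2 was 2.58-fold higher. This call was lost with total-read scaling (adjusted p = 0.111) and without the low-value filter (adjusted p = 0.108). With total-read scaling the mean log2 fold change was -0.87, against -0.71, and 11 of the 15 genes fell; without the filter it was -0.52, and 10 of 19 genes fell and 7 rose, with a median of -0.34 against -0.93. Of 7 Notch pathway genes 5 rose and 2 fell (5 up and 2 down adjusted over the list alone; camera adjusted p = 0.0788). The target genes Hey1 and Hes1 were 14.4-fold and 2.29-fold higher, the ligand gene Jag1 3.11-fold higher and Rbpj 1.92-fold lower. Of 22 secreted growth factors 7 rose and 7 fell (7 up and 7 down adjusted over the list alone; camera adjusted p = 0.893), and 6 rose and 12 fell with total-read scaling. Pdgfb rose 11.5-fold to 5.43 ± 0.625 RPKM, while Igf2 was 99.1-fold lower and Fgf10 6.14-fold lower. Of 11 cytokines and chemokines 6 rose and 4 fell (6 up and 4 down adjusted over the list alone; camera adjusted p = 0.710). Il33 was 4.49-fold and Cxcl12 2.89-fold higher and the neutrophil chemokine genes Cxcl1 and Cxcl5 3.40-fold and 3.08-fold lower. Of 15 interferon response genes 8 fell and 2 rose (8 down and 2 up adjusted over the list alone; camera adjusted p = 0.0709). Of 13 immediate early and heat shock genes 6 rose and 1, Nr4a1, fell (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.151). The median log2 fold change of the immediate early list was 0.10, and -0.08 with total-read scaling. In the interferon list, Ifit3 and Oasl2 were 1.72-fold and 2.52-fold lower, and 0 of the 15 genes passed limma's test against a 1.5-fold change (0 at an unadjusted p under 0.05).

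**Figure D2:**
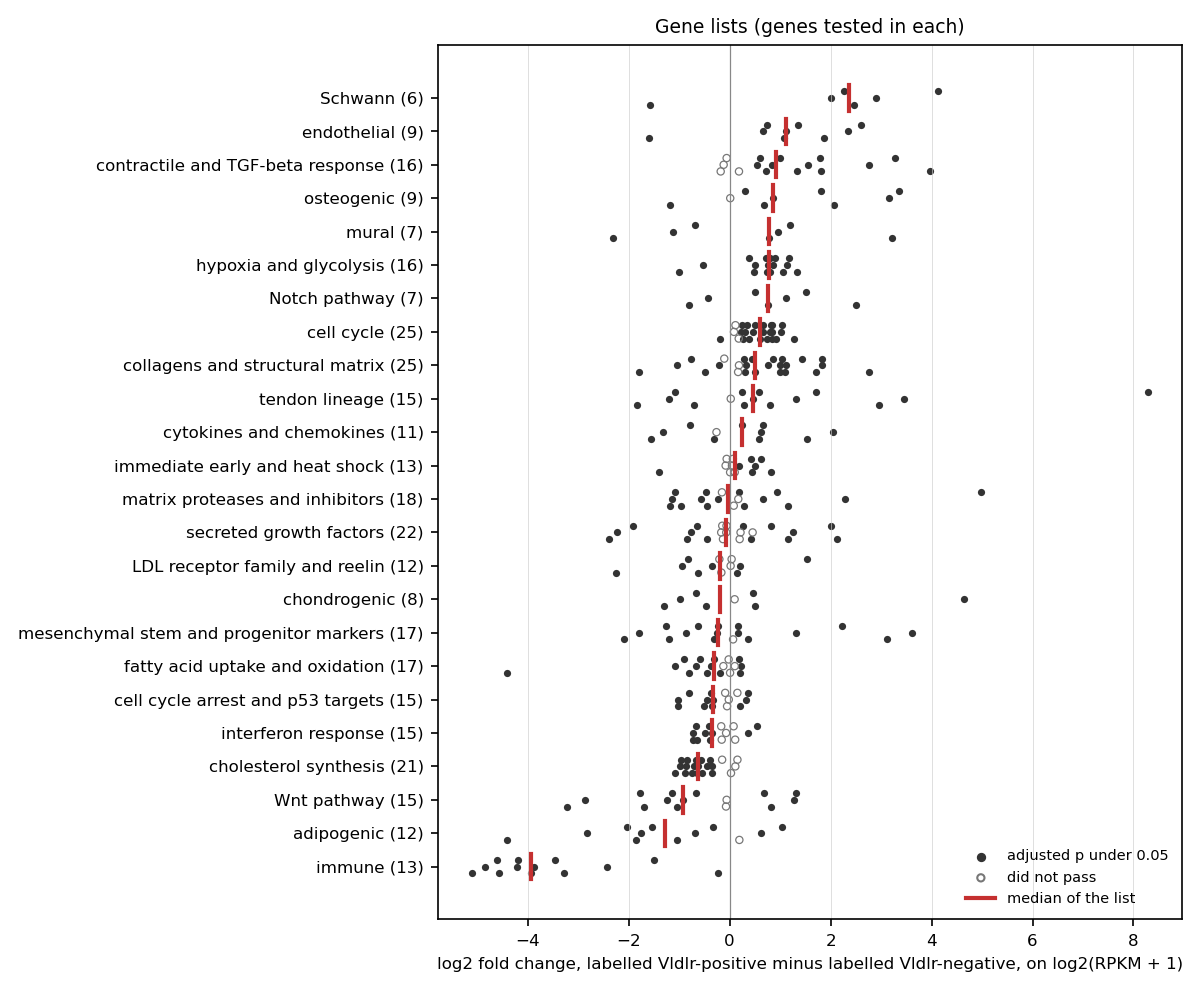
Log2 fold change on the log2(RPKM + 1) scale (x axis, labelled-positive minus labelled-negative) of each tested gene in the 24 lists (y axis, with the number tested); filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. The medians run from -3.93 for the immune list to 2.37 for the Schwann list.

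Markers of other cell types differed between the groups and moved in opposite directions. All 13 tested genes of the immune list fell (0 up and 13 down adjusted over the list alone; camera adjusted p = 9.7e-12, adjusted p = 0.155 with an estimated correlation). The lysozyme gene Lyz2 was at 429.8 ± 38.5 RPKM in the labelled-negative and 27.4 ± 3.09 RPKM in the labelled-positive libraries, Ctss at 35.9 ± 4.39 and 0.0739 ± 0.0924 RPKM, and Fcer1g at 19.9 ± 1.51 and 0.138 ± 0.00072 RPKM. The complement genes C1qa and C1qb, at 24.0 ± 2.28 and 29.1 ± 3.56 RPKM in the labelled-negative libraries, had 3 and 2 reads in all labelled-positive libraries together, and Tyrobp, at 23.5 ± 4.23 RPKM, had 0, at least 260-fold lower. In the Schwann list 5 of 6 genes rose and 1 fell (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0027, adjusted p = 0.155 with an estimated correlation). The glial transcription factor genes Sox10 and Foxd3 were at 16.8 ± 1.70 and 6.63 ± 1.17 RPKM in the labelled-positive libraries and had 2 reads each in all labelled-negative ones, Erbb3 was 40.5-fold higher, and S100b was 3.42-fold lower. In the endothelial list 8 of 9 genes rose and 1 fell (8 up and 1 down adjusted over the list alone; camera adjusted p = 2.9e-04, adjusted p = 0.155 with an estimated correlation). The cadherin gene Cdh5 was at 5.07 ± 0.195 RPKM against 0 reads, at least 396-fold higher, Emcn at 4.20 ± 0.277 RPKM and Pecam1 at 2.69 ± 0.0323 RPKM.

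Of 7 mural cell genes 4 rose and 3 fell (4 up and 3 down adjusted over the list alone; camera adjusted p = 0.710). Ndufa4l2 was 9.70-fold and Pdgfrb 1.95-fold higher and Steap4 5.10-fold lower. The list's median (0.77) and mean were above 0 and fry pointed down; without the low-value filter 4 rose and 5 fell, with a median of -0.39. Of 4 listed skeletal muscle genes 0 passed the filter, with Acta1 at 0.687 ± 0.253 and 0.800 ± 0.200 RPKM and Mylpf at 0.287 ± 0.0291 and 0.625 ± 0.168 RPKM. Of 4 listed epithelial genes 1 was tested, Perp, which fell 8.52-fold to 2.72 ± 0.281 RPKM, and 0 genes of the erythroid list were in the table. Y-linked genes and Xist were chosen after their values were seen. Ddx3y was at 10.3 RPKM in the labelled-negative and 0.0116 RPKM in the labelled-positive libraries, while Xist, the RNA of the inactive X chromosome of female cells, was at 18.8 RPKM or more in all 6.

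With an estimated correlation, 0 of the 24 lists passed camera in limma (5 had an unadjusted p under 0.05), while 13 passed with the preset correlation and 22 passed fry. Against a 1.5-fold change, 11 collagens and structural matrix genes rose and 2 fell, 9 contractile and TGF-beta response genes rose, 6 hypoxia and glycolysis genes rose and 1 fell, 3 fatty acid genes fell, 3 arrest genes fell and 1 immediate early gene fell. In the same test 6 tendon lineage genes rose and 3 fell, and 4 progenitor markers rose and 5 fell. For proteases 4 rose and 4 fell, for cytokines 2 rose and 3 fell, and for Notch 3 rose and 0 fell. Secreted growth factors had a median and a mean below 0 and a fry direction above 0.

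**Figure D3:**
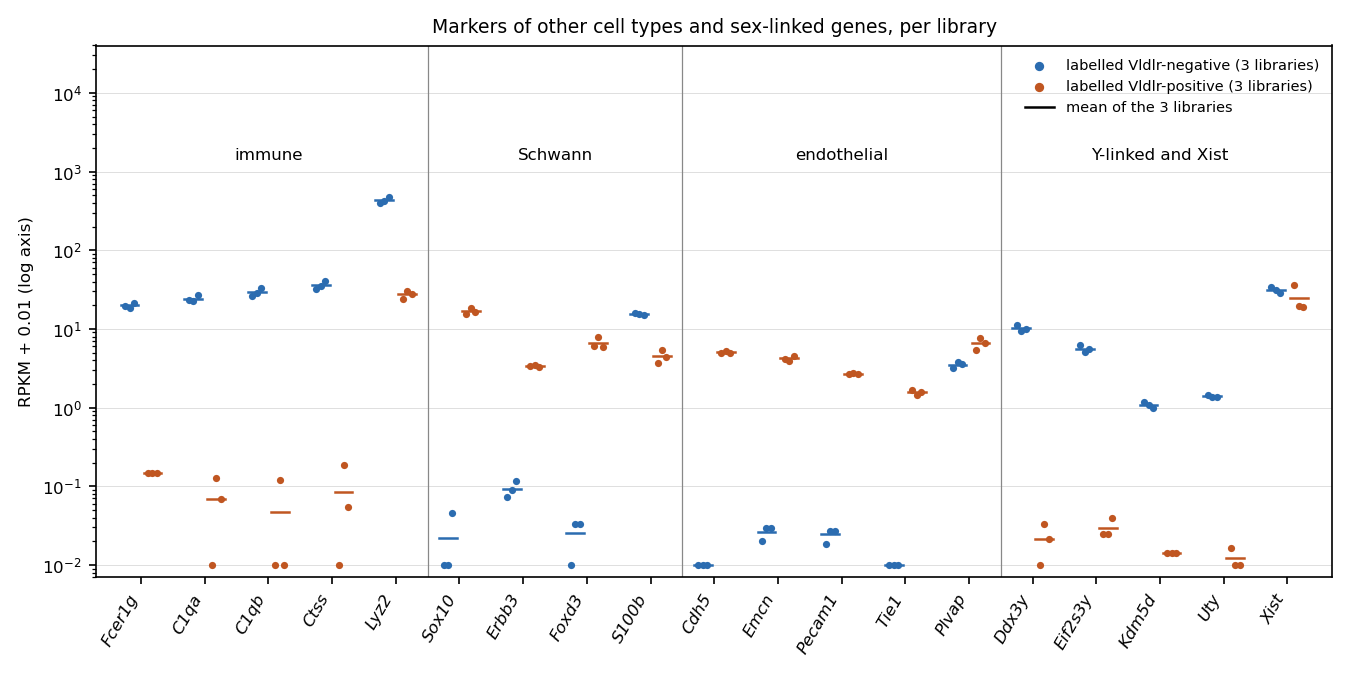
RPKM + 0.01 per library (log axis) of immune, Schwann and endothelial markers and of the 4 Y-linked genes and Xist; blue points are the 3 labelled-negative and orange points the 3 labelled-positive libraries, and short lines are group means. The immune and Y-linked genes lie higher in the labelled-negative libraries, most Schwann and all shown endothelial genes higher in the labelled-positive ones, and Xist is read in all 6.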

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

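The test against a 1.5-fold change and the addition of 5 RPKM to Vldlr were chosen after the result was seen; the other alternatives were planned. Scaled by total reads only, 1875 genes were higher and 5547 lower in the labelled-positive libraries, because the composition factors were left out. Genes at least 2-fold lower numbered 728 with a pseudocount of 0.1 and 763 with limma voom. With the 5 RPKM filter, which tests fewer genes, 1800 were lower, 262 of them at least 2-fold. Against a 1.5-fold change, 537 were higher and 606 lower, and Col1a1 (0.76) had an adjusted p of 0.150. Of the 6769 genes called, 0 were called in the other direction under any alternative except Vldlr, at -0.41 with 5 RPKM added; 181 had a fold change of the other sign, without such a call, with total-read scaling. Leaving out each library in turn gave 5245 to 7857 called genes in all, the most without labelled-positive replicate 1. With an estimated correlation, which also lowered camera's degrees of freedom, 0 lists were called. Fry, which does not compare a list with other genes, called 22. The direction camera gave turned only for lists that were not called, with these mean log2 changes: matrix proteases 0.0563 with total-read scaling and 0.25 without the filter, progenitor markers -0.0360 with total-read scaling and 0.34 at 5 RPKM, the chondrogenic list 0.0719 with total-read scaling and 0.20 without the filter, and mural genes 0.0803 without the filter. For growth factors these were -0.21 with total-read scaling, -0.0410 without the filter and -0.0973 to -0.00462 with a library left out, turning without labelled-positive replicate 2. The cause was not tested. The Wnt call was lost with total reads (adjusted p 0.111) and without the filter (0.108); Notch was gained with both (0.00893 and 0.00833), cell cycle arrest at 5 RPKM (0.0413) and without labelled-positive replicate 2 (0.0459), and interferon without labelled-positive replicate 3 (0.0134), none of them with an estimated correlation. 14 named genes lost their call, all against a 1.5-fold change. The replicate number as a block gave 3738 higher and 3315 lower. Deviations of same-numbered libraries correlated at 0.303, -0.0611 and 0.307, and those of libraries with unlike numbers at -0.387 to 0.265. These ranges overlap and do not decide whether the numbers mark pairs. The main fit had no block, as planned. The planned edgeR count test was not run, because the rule fixed for normalized values was followed. The worked-out reads were tested with limma voom only.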

Other observations

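The genes of the next paragraph and the tests on Y-linked genes and, except for the order of genes in the table, on Vldlr were chosen after the result was seen, as were the tests of scaling and of the share of tendon cells for the macrophage genes.

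Single genes picked for their values, which say nothing of a group, included limb transcription factor genes that were lower in the labelled-positive libraries. Tbx4, a hindlimb transcription factor gene, was at 7.71 ± 0.399 against 20.4 ± 0.835 RPKM (2.65-fold lower), Tbx5, its forelimb paralog, was 4.71-fold lower, Tbx18 was 2.41-fold lower, and the hindlimb gene Pitx1 was at 12.8 against 23.1 RPKM. Hoxa11, Hoxb9 and Hoxc8 also fell, while Hoxc10, at 29.1 against 32.4 RPKM, did not pass (limma adjusted p = 0.0691). Of the axon guidance genes picked, Slit2 was 9.37-fold, Sema3d 7.68-fold and Sema3c 4.33-fold lower, and Slit3 did not pass, at 41.1 against 40.6 RPKM. Sox2, a transcription factor gene of neural and glial progenitors, was 170-fold higher at 7.41 RPKM, and the adhesion genes L1cam and Ncam1 were 12.6-fold and 3.69-fold higher, while the glial marker S100b was 3.42-fold lower.

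Macrophage genes were read in the labelled-negative libraries and were nearly absent from the labelled-positive ones, although a sort for Col1a1-lineage cells would be expected to remove macrophages. Depth or scaling is argued against, since the immune list's median was -4.12 with total-read scaling. A lower share of tendon cells that raises the markers of every other cell type is argued against too. The Schwann and endothelial lists moved the other way, with medians of 2.37 and 1.11. These lists cannot show whether the share of tendon cells itself was lower, because each follows only its own cell type. Of 17 macrophage genes outside the fixed list, 16 (94.1%) were at least 4-fold lower, against 4.00% of all genes, and Lyz2 was the most abundant marker at 429.8 RPKM. Macrophages among the labelled-negative cultures are a candidate source; expression of these genes by the tendon cells themselves was not tested.

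The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in the labelled-negative libraries, and the labelled-positive ones had 11 such reads against 5941, or 0.185%. A lower yield through mapping or depth is argued against by so small a share at like depth. The smallest fold was 269, for Kdm5d (3 reads in the labelled-positive libraries; 95% counting interval 91.7 to 1307). Xist was at 34.3, 31.5 and 28.4 RPKM in the labelled-negative and 36.6, 19.3 and 18.8 RPKM in the labelled-positive libraries, a ratio of means of 1.26 (limma adjusted p = 0.173), so it was not lower where male cells would lower it. Cells of both sexes in the labelled-negative cultures and female cells in the labelled-positive ones may still account for the Y-linked genes, but these values do not decide it, and loss of the Y chromosome in culture was not tested. If donors or cultures differed between the groups, that difference is confounded with the sort label for all genes called, not only for the Y-linked ones.

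The labelled-negative values of Vldlr were the only values off whole reads. Counting of reads in parts is argued against by 0 other genes off whole reads among 15690, and another exon length by 0 of 39801 lengths tried fitting all 3 values (0.318 expected by chance). Of the whole-number amounts from 1 to 100 RPKM, 1 made all 3 values whole, namely 5, against 0.0008 expected by chance, so a fixed amount of 5 RPKM taken from each value after the reads were turned into RPKM is a candidate explanation; why is not known. The order of genes in the table followed the p-values of limma voom on the worked-out reads (Spearman correlation 0.990). It was therefore taken as an order by p, which the table itself does not state. In this voom test, 7.5% of the 200 genes around Vldlr had a smaller p than Vldlr as listed. With 5 RPKM added to Vldlr, 71.5% had a smaller p. Both p-values lay inside the range of these genes, so whether the values came before or after the ordering cannot be told apart. Whether mRNA after culture follows the surface protein, and whether the group labels were exchanged, was not tested.

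H19, Igf2, Cdkn1c and Plagl1, all imprinted, were lower in the labelled-positive libraries, and the hypothesis that imprinted genes fell as a group was tested on 13 others. Of these, 9 (69.2%) fell and 0 rose, against 26.1% of all tested genes that fell (exact hypergeometric p = 0.00139, with genes that are not independent). The falls were uneven in size. Peg3 was at 2.29 against 11.7 RPKM and Dlk1 at 0.701 against 5.01 RPKM. Smaller falls were those of Mest, at 92.1 against 116 RPKM, Ndn, at 37.4 against 50.1 RPKM, and Rian, at 8.13 against 11.5 RPKM. Gnas, Sgce, Peg10 and Snrpn did not pass. A difference in sex or cell type between the groups stays open as an explanation.

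Of the 10 splits of the 6 libraries, 1, the real one, called as many genes (6769; highest other split 0 in limma), and 10 splits are too few for a share under 0.05.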
